A study of Homo sapiens with 6 samples.

How the data were processed

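Libraries were made from monocytes and M-MDSC of 3 patients with non-small cell lung cancer, 1 library of each population per patient. Per the labels' protocols, total RNA was extracted from cell pellets with a column kit and DNase treatment, and 3' mRNA libraries were made with the Lexogen QuantSeq FWD kit, which primes on the poly(A) tail and reads near the 3' end, so that a transcript gives about 1 fragment whatever its length. The authors deposited a table of estimated counts (expected counts) per Ensembl gene for the 6 libraries. Per the submitters' processing notes, Bowtie2, RSEM 1.2.31, DESeq2 and the genome build hg19 were used, with no role or order given. RSEM shares reads that match several genes between them, so values of overlapping genes and near-identical copies are uncertain. The deposited values are whole numbers, whereas RSEM's estimates are not, and where they were rounded is not given in the sources used here, nor are the annotation release, the trimming and the use of strand. Antisense and overlapping genes can therefore not be told apart by these counts. No molecular identifiers are named, so counts include PCR copies, and intervals and floors cover counting error only.

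The table held 57736 gene IDs. A table of gene names gave 51959 of them a symbol, GENCODE 29 gave 342 more, and 5435 had none, so 90.59% had a symbol. The IDs without a symbol took 2.63% to 2.93% of the counts of a library. The build of that annotation differs from hg19, so it served for names only and no coordinates are given. Tests left out 475 sex-linked IDs. Another 595 IDs whose level can reflect a single donor (classical HLA class I genes, HLA-DRB3, HLA-DRB4 and HLA-DRB5, immunoglobulin and T cell receptor segments, genes commonly deleted in whole) were tested and are not named. All 6 columns of values were used.

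Groups and replicate numbers came from the labels, and a replicate number is the number of a patient. Estimated counts were rounded to whole numbers, filtered with edgeR's filterByExpr, which left 16303 genes, and scaled by TMM, with factors of 0.954 to 1.08. Genes were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) with the group as the only term and Benjamini-Hochberg adjustment, at an adjusted p of 0.05. Standard errors are the log2 change over the square root of the F value. The fit with the patient as a block left 2 residual degrees of freedom against 4 without it, and its common dispersion was 0.148 against 0.195. The pairing comes from the labels, which give the same patient to a monocyte and an M-MDSC library. In a check, deviations from the group means correlated across genes by 0.153, 0.172 and 0.202 between libraries of the same patient. Between libraries of different patients in the 2 groups they correlated by at most -0.029. The deviations of a group sum to 0, so positive values for the same patient push the others below 0 on balance. The 2 sides of this check are therefore not independent. Blocked values stand beside calls over all genes and list tests that they change. Counts adjusted over a list alone or by unadjusted p are without the block unless stated. Within a group, counts of any 2 libraries differed by far more than sampling noise (chi-square per degree of freedom 34.7 to 63.3), so each library counted as 1 replicate, and log2 CPM correlated by 0.896 to 0.918.

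The tests, the groups, 32 gene lists written from general knowledge, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold, with the same sign in all 3 pairs and at least 5 CPM in the higher group. It added up to 4 members past the threshold, or the 2 with the smallest p, from each list past its own threshold, the 2 with the smallest p from each other list, and 17 genes that define these cells. Some genes that the rule takes are not reported here. Lists with at least 3 measured genes were tested 2-sided with camera (limma 3.58.1, preset correlation 0.01), which compares a list with all other genes. Camera was repeated with a correlation estimated from the residuals, and fry was run beside it, which tests whether a list's genes move on balance 1 way without comparing them with other genes. The lists cover MHC class II, neutrophil granules and mature neutrophils, classical and non-classical monocytes, suppressive mediators, stress, interferon and inflammatory responses, metabolism, cell cycle, transcription factors, other blood cells, checkpoint molecules, MHC class I processing, adhesion, ribosomal proteins and antioxidants.

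The tests were run first on simulated counts with 200 genes changed by known folds, drawn from the means and depths of these libraries. Genes raised 4-fold had a median fitted log2 change of 1.99 without the block (15479 genes in the step) and 2.03 with it (15570 genes). Alternatives were the patient block, DESeq2's size factors, no filter, a stricter filter of at least 5 CPM in 3 libraries, limma-voom, DESeq2 1.42.0, an adjusted p of 0.1, a test against a fold of 1.5, and leaving out each library or each pair. Where a group had no counts for a gene, the fold was bounded by 3 counts over the group. Where it had 1 to 3, the ratio of summed counts is given with an exact 95% interval.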

Results

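Gene expression was measured by 3' RNA sequencing in 2 populations of myeloid cells from 3 patients with non-small cell lung cancer. The populations were monocytes and monocytic myeloid-derived suppressor cells (M-MDSC), which are cells of monocyte morphology that restrain T cells in people with cancer. Each patient gave 1 library of each population, so the 6 libraries formed 2 groups of 3 and 3 matched pairs. The replicates of a group came from separate patients, per the labels. The series title places the work in the question of whether monocyte-like cells are precursors of granulocytic suppressor cells. The total estimated count was 15527247, 14754683 and 15294863 in monocyte replicates 1, 2 and 3, and 13635449, 15267082 and 13974364 in M-MDSC replicates 1, 2 and 3. Between 18521 and 19257 genes had at least 1 count in a library. The 10 most abundant genes took 8.80% to 12.2% of the counts. Levels below are mean counts-per-million values (CPM) ± SD with n = 3 per group, and fold changes are M-MDSC against monocytes with their standard error (SE).

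As lists, neutrophil secondary and tertiary granule, mature neutrophil and classical monocyte genes were higher in M-MDSC, and MHC class II, non-classical monocyte, dendritic cell and macrophage genes were lower. These were the 7 of 31 lists past the threshold with an estimated correlation, and 0 passed that test with the patient block. With 2 residual degrees of freedom, its adjusted p was 0.0922 for each of the 7, the lowest of any list. Fry with the block called all 7. Of their members, 2 of 6, 1 of 18, 4 of 18, 5 of 13, 4 of 16, 0 of 13 and 2 of 12 passed over all genes, in that order. PADI4, the enzyme that turns arginine into citrulline in histones, rose from 9.56 ± 6.28 to 90.6 ± 35.1 CPM. S100A12, a calcium-binding alarmin of neutrophils and monocytes, rose from 174 ± 57.0 to 758 ± 177 CPM, a log2 change of 2.12 ± 0.28 (SE). HLA-DRA, the alpha chain of HLA-DR, fell from 6098 ± 1072 to 1228 ± 460 CPM, a log2 change of -2.31 ± 0.29. FCGR3A, the Fc receptor CD16a of non-classical monocytes and NK cells, fell from 343 ± 170 to 26.9 ± 15.1 CPM, a log2 change of -3.67 ± 0.48. With edgeR's quasi-likelihood test and no patient term, 34 of 16303 genes passed an adjusted p of 0.05, 17 higher and 17 lower. An unadjusted p under 0.05 was reached by 1142 genes, and by 2181 with the patient as a block, against 815 expected if no gene differed. With the patient as a block, 547 genes passed, 279 higher and 268 lower, and these held all 34. All 34 and all 547 had the same sign in the 3 pairs. The blocked fit favours genes whose differences within the pairs agree, so the shared sign adds no separate support to the 547. The unblocked count changed when single libraries were left out. It was 1, 10 and 22 without M-MDSC replicate 2, 3 and 1, and 2, 23 and 37 without monocyte replicate 1, 3 and 2. In simulated libraries of these groups with 15479 genes in the step, the unblocked test recovered 8 of 67 genes changed 2-fold, 33 of 67 changed 4-fold and 52 of 66 changed 8-fold, with 8 unchanged genes called. The blocked test, with 15570 genes in the step, recovered 31 of 67, 44 of 67 and 57 of 66, with 20 unchanged genes called. Each test had its own simulated counts, with other genes changed and the dispersion of its own fit. Patient deviations entered only the counts of the blocked test, so the recoveries do not rank the 2 tests. In both simulations unchanged genes were a larger share of the calls than the nominal 0.05, a limit on the 34 unblocked and the 547 blocked calls.

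**Figure D1:**
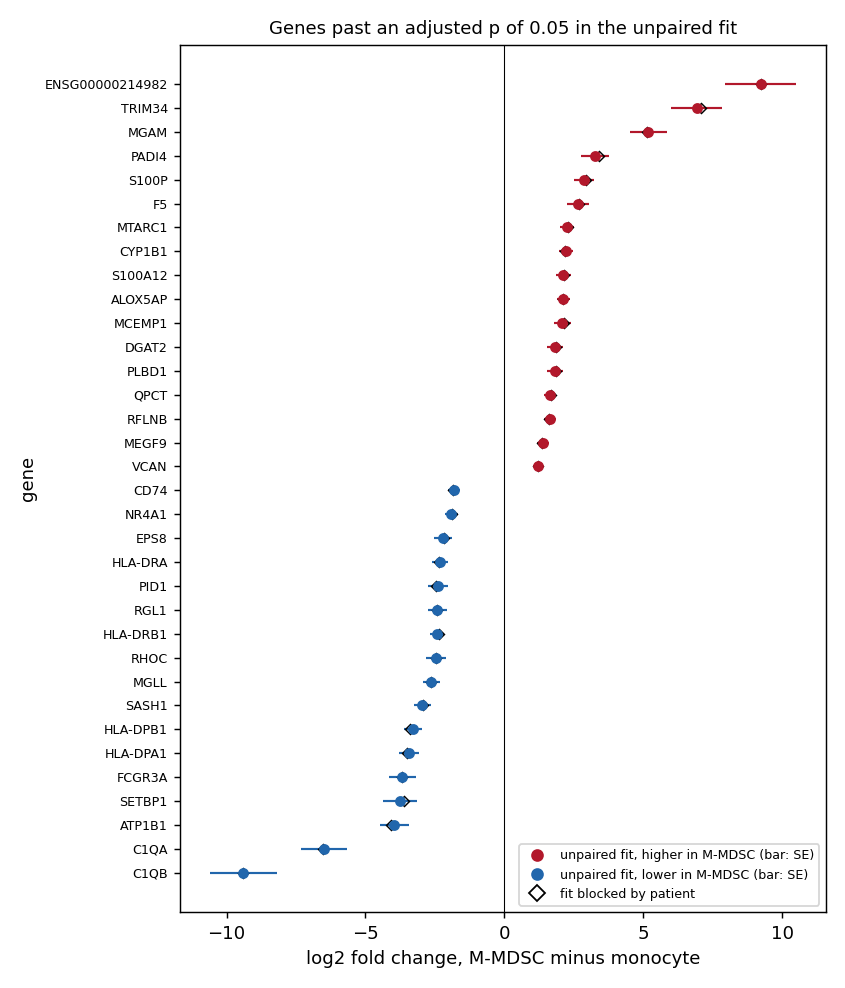
The log2 fold change of M-MDSC against monocytes (x axis) is plotted for each of the 34 genes past an adjusted p of 0.05 without a patient term (y axis), as a point with its SE in red for higher and blue for lower, with an open diamond for the fit blocked by patient. C1QB and ENSG00000214982 have no counts in 1 of the groups, so the size of their fitted change depends on the prior count and is no measured fold, and HLA-DRA lies at -2.31 and S100A12 at 2.12.

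Among the genes with the largest rise past the unblocked threshold, MGAM, an alpha-glucosidase also held in neutrophil granules, went from 0.639 ± 0.517 to 23.8 ± 13.9 CPM (log2 5.18 ± 0.66, adjusted p = 0.0174). Its call was lost with limma-voom (adjusted p = 0.424) and without monocyte replicate 1 (0.106), M-MDSC replicate 2 (0.0911) or M-MDSC replicate 3 (0.0682). PADI4 had a log2 change of 3.25 ± 0.51 (adjusted p = 0.0447). Its call was lost without monocyte replicate 1 (0.0729) or 2 (0.129), and without M-MDSC replicate 1 (0.0683), 2 (0.174) or 3 (0.119). S100P, a calcium-binding protein of the same family as S100A12, rose from 8.61 ± 4.12 to 62.1 ± 4.73 CPM. F5, which encodes coagulation factor V, rose from 23.3 ± 12.3 to 146 ± 45.4 CPM. CYP1B1, a cytochrome P450 enzyme, rose from 131 ± 7.71 to 614 ± 200 CPM. ALOX5AP, needed for leukotriene synthesis, rose from 25.5 ± 3.96 to 111 ± 27.0 CPM, and DGAT2, which makes triglycerides, from 10.1 ± 3.27 to 35.8 ± 5.85 CPM. MTARC1, MCEMP1 and PLBD1 had log2 changes of 2.24 ± 0.26, 2.08 ± 0.31 and 1.82 ± 0.28. S100P, F5, CYP1B1, ALOX5AP, DGAT2, MTARC1 and MCEMP1 lost their calls in at least 1 fit with a library left out. PLBD1 lost its call without any 1 of the 6 libraries. TRIM34 also passed, with 3 counts in the monocytes and 395 in the M-MDSC, a ratio of 139 with a 95% counting interval of 47.2 to 676, while the overlapping read-through gene TRIM6-TRIM34 had 660 and 129 counts. The summed counts of TRIM34, TRIM6-TRIM34 and TRIM6 were 14.6 ± 6.37 CPM in monocytes and 12.5 ± 2.31 CPM in M-MDSC (log2 -0.23 ± 0.35), which did not pass. TRIM34 itself lost its call with limma-voom (adjusted p = 0.156), and without monocyte replicate 1 or any 1 of the M-MDSC libraries. The identifier ENSG00000214982, which had no symbol here and was singled out after its values were seen, had 0 counts in monocytes and 220 in M-MDSC, at least 77.4-fold higher when the zero is set to 3 counts over the group.

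Among the genes with the largest fall, C1QA, a chain of complement component C1q, went from 39.6 ± 13.9 to 0.423 ± 0.669 CPM (log2 -6.48 ± 0.83, adjusted p = 0.0174). Its M-MDSC level lay near the floor, at 0.0754, 0 and 1.19 CPM in replicates 1, 2 and 3, so the size of the fold is uncertain. The call of C1QA was lost with limma-voom (adjusted p = 0.334) and without monocyte replicate 1 (0.0971), M-MDSC replicate 1 (0.0584) or M-MDSC replicate 2 (0.0671). C1QB, another chain of C1q, had 260 counts in monocytes and 0 in M-MDSC, at least 82.2-fold lower against the same floor, and its call was lost with limma-voom (adjusted p = 0.184) and without any 1 of the 6 libraries. ATP1B1, a subunit of the sodium-potassium pump, fell from 24.7 ± 8.06 to 1.58 ± 0.976 CPM, and SETBP1 from 9.61 ± 5.61 to 0.705 ± 0.183 CPM. SASH1 fell from 65.4 ± 22.2 to 8.38 ± 1.92 CPM (log2 -2.96 ± 0.30, adjusted p = 0.0130). MGLL, which breaks down monoacylglycerols, fell from 31.6 ± 7.79 to 5.11 ± 1.23 CPM. The small GTPase RHOC and RGL1 had log2 changes of -2.46 ± 0.37 and -2.41 ± 0.33. With limma-voom ATP1B1, SETBP1, RHOC and RGL1 also lost their calls (adjusted p = 0.0918, 0.447, 0.0554 and 0.0709). ATP1B1, SETBP1, SASH1, MGLL and FCGR3A lost theirs in at least 1 fit with a library left out. RHOC and RGL1 lost theirs without any 1 of the 6 libraries. FCGR3A shares almost all of its sequence with FCGR3B, and their summed counts fell from 345 ± 169 to 28.7 ± 15.4 CPM (log2 -3.59 ± 0.46, adjusted p = 0.0174).

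The list of MHC class II antigen presentation genes was lower in M-MDSC. Of its 13 measured members, 5 fell over all genes tested (5 with limma-voom and 8 with DESeq2), 10 when adjusted over the list alone, and 11 over all genes with the patient block. HLA-DPA1 fell from 923 ± 231 to 85.4 ± 41.9 CPM, HLA-DPB1 from 831 ± 62.7 to 85.4 ± 39.3 CPM and CD74, the invariant chain, from 2628 ± 289 to 745 ± 197 CPM. HLA-DRB1, whose reads can be split with its near-identical copies, had a log2 change of -2.41 ± 0.26. The 5 calls over all genes were lost without M-MDSC replicate 2, and all but that of HLA-DRB1 without monocyte replicate 1. CIITA, the transcription factor that switches these genes on, went from 126 ± 29.1 to 52.0 ± 20.6 CPM, not past the threshold without the block (adjusted p = 0.170) and lower with it (adjusted p = 1.58e-04). The median log2 change of the list was -1.82 (adjusted p = 0.0145 with an estimated correlation, and 0.0922 with the block). Low surface HLA-DR is commonly used to sort M-MDSC, and the labels do not state the gate.

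Markers of non-classical monocytes, dendritic cells and macrophages were lower in M-MDSC as lists. Of 16 measured non-classical monocyte markers, 4 fell over all genes (FCGR3A, RHOC, C1QA and C1QB), 2 with limma-voom, 9 with DESeq2, 11 adjusted over the list alone and 11 over all genes with the patient block (median log2 -1.51, adjusted p = 0.0145 with an estimated correlation, and 0.0922 with the block). CDKN1C, a cell cycle inhibitor, went from 109 ± 43.8 to 13.8 ± 9.34 CPM, which passed with the block (adjusted p = 0.00120) and missed without it (adjusted p = 0.0504). CSF1R, the receptor for macrophage colony-stimulating factor, went from 111 ± 29.1 to 44.8 ± 14.0 CPM (adjusted p = 0.125, and 1.56e-04 with the block). Of 13 measured dendritic cell markers, 0 passed over all genes with edgeR or limma-voom, 7 had an unadjusted p under 0.05, 4 fell with DESeq2, 5 fell adjusted over the list alone and 4 over all genes with the block (median log2 -1.0, adjusted p = 0.0145 with an estimated correlation, and 0.0922 with the block). CD1C, a lipid-presenting molecule of conventional dendritic cells, went from 25.7 ± 19.1 to 4.55 ± 0.995 CPM (adjusted p = 0.110, and 0.00102 with the block). ENHO had 202 counts in monocytes and 1 in M-MDSC, a ratio of 191 with a 95% counting interval of 34.0 to 7600 (adjusted p = 0.0504, and 0.00923 with the block). Of 12 measured macrophage markers, 2 fell over all genes, C1QA and C1QB, which the non-classical list also holds, 0 with limma-voom, 3 with DESeq2, 5 adjusted over the list alone and 5 over all genes with the block (median log2 -1.22, adjusted p = 0.0173 with an estimated correlation, and 0.0922 with the block). VSIG4, a complement receptor of macrophages, went from 26.0 ± 31 to 0.845 ± 0.794 CPM (adjusted p = 0.128, and 0.00737 with the block).

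Of the 3 neutrophil lists, 2 were higher in M-MDSC with an estimated correlation. Of 6 measured secondary and tertiary granule genes, 2 rose over all genes (PADI4 and QPCT), 2 with limma-voom, 3 with DESeq2, 5 adjusted over the list alone and 4 over all genes with the patient block (median log2 1.85, adjusted p = 0.0387 with an estimated correlation, and 0.0922 with the block). QPCT, glutaminyl cyclase, rose from 47.8 ± 12.6 to 150 ± 11 CPM. Its call was kept without monocyte replicate 3 and lost without any other single library. PADI4 is on this list although its product acts on histones. The member CAMP passed in neither fit (adjusted p = 0.977, and 0.780 with the block). HP, haptoglobin, rose with the block from 5.92 ± 8.33 to 51.2 ± 31.7 CPM (adjusted p = 0.361, and 1.23e-04 with the block). The other 13 of the 19 granule genes on the list were not among the genes tested, including LTF, LCN2, CEACAM8, MMP8 and ARG1. Of 18 measured mature neutrophil genes, 1 rose over all genes (MGAM), 1 with limma-voom (not MGAM), 5 with DESeq2, 8 adjusted over the list alone and 8 over all genes with the block (median log2 0.92, adjusted p = 0.0145 with an estimated correlation, and 0.0922 with the block). PROK2, a secreted chemoattractant, rose with the block from 20.2 ± 15.1 to 127 ± 44.7 CPM (adjusted p = 0.0778, and 6.53e-06 with the block), and VNN2, a surface pantetheinase, from 162 ± 126 to 638 ± 249 CPM (adjusted p = 0.338, and 1.15e-04 with the block). CSF3R, the receptor for granulocyte colony-stimulating factor, went from 258 ± 53.8 to 417 ± 51.6 CPM (adjusted p = 0.343, and 0.00452 with the block). CXCR2, a receptor for CXCL8, was 8.86 ± 2.26 and 17.3 ± 3.87 CPM and passed in neither fit (adjusted p = 0.442, and 0.0904 with the block). CXCR1, the other receptor for CXCL8, had 0 counts in monocytes and 31 in M-MDSC, under the filter for testing. Of 7 measured primary granule genes, 0 passed over all genes with edgeR or limma-voom, 2 had an unadjusted p under 0.05, 1 rose with DESeq2, 2 rose adjusted over the list alone and 2 over all genes with the block. The call of this list was lost with an estimated correlation (adjusted p = 0.110). These 2 were BPI, a bactericidal protein, at 4.30 ± 2.99 and 24.7 ± 5.62 CPM (adjusted p = 0.131, and 9.37e-04 with the block), and SERPINB10, at 9.69 ± 2.37 and 22.1 ± 7.43 CPM (adjusted p = 0.300, and 0.0215 with the block). MPO, myeloperoxidase, was 5.35 ± 2.94 and 8.94 ± 3.18 CPM and passed in neither fit, and ELANE, neutrophil elastase, had 0 counts in both groups.

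Classical monocyte markers were higher in M-MDSC as a list. Of 18 measured, 4 rose over all genes (ALOX5AP, S100A12, PLBD1 and VCAN), 4 with limma-voom, 7 rose and 1 fell with DESeq2, 8 rose and 2 fell adjusted over the list alone, and 12 rose and 1 fell over all genes with the patient block (median log2 0.75, adjusted p = 0.0202 with an estimated correlation, and 0.0922 with the block). VCAN, the proteoglycan versican, rose from 1914 ± 305 to 4410 ± 612 CPM (log2 1.2 ± 0.19, adjusted p = 0.0448, and 0.0525 with the stricter filter). Its call was also lost without any 1 of the 6 libraries. The calprotectin chains S100A8 and S100A9 rose with the block, from 2208 ± 965 to 7129 ± 1963 CPM (adjusted p = 0.125, and 1.92e-05 with the block) and from 1062 ± 563 to 3011 ± 854 CPM (adjusted p = 0.306, and 2.98e-04 with the block). CD14, a co-receptor for lipopolysaccharide and the usual marker of these cells, was 784 ± 427 and 1232 ± 385 CPM (adjusted p = 0.859, and 0.0121 with the block). LYZ, lysozyme, was 7104 ± 2813 and 9300 ± 3971 CPM and passed in neither fit (adjusted p = 0.945, and 0.0715 with the block). FCN1, CCR2 and CD163 had log2 changes of 0.10 ± 0.18, 0.11 ± 0.40 and 0.11 ± 0.22 and passed in neither fit. The member that fell with the block was CSF1R.

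**Figure D2:**
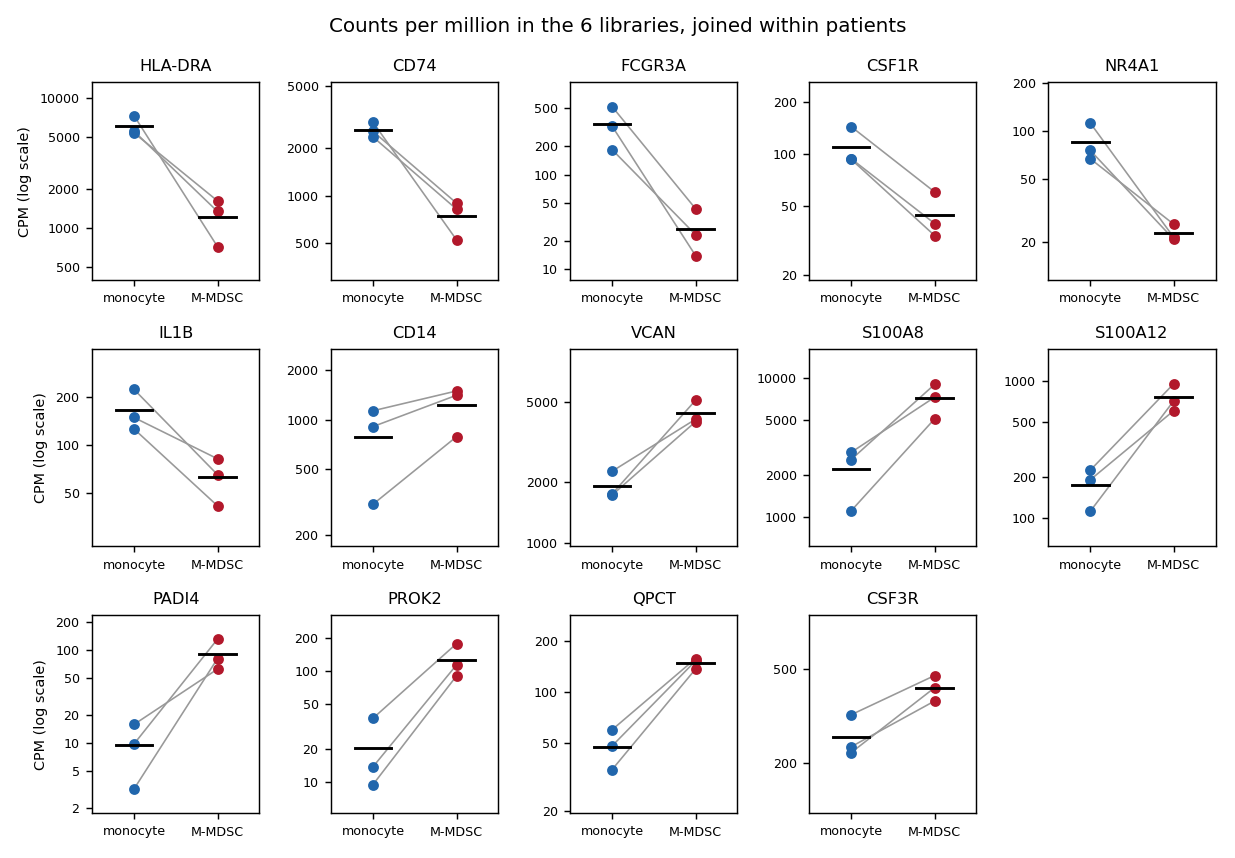
CPM on a log axis is plotted for 14 genes in the 3 monocyte libraries (blue) and the 3 M-MDSC libraries (red), with grey lines joining the libraries of a patient and black bars at the group means. All 3 lines go down for HLA-DRA (mean 6098 to 1228), CD74, FCGR3A, CSF1R, NR4A1 and IL1B and up for the other genes.

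Genes tied to the suppressive function of such cells were tested as a list of 22 measured members. With the preset correlation the list was higher in M-MDSC (median log2 0.21), a call lost with an estimated correlation (adjusted p = 0.142). Of its members, 0 passed over all genes with edgeR or limma-voom, 7 had an unadjusted p under 0.05, 3 rose with DESeq2, 4 rose adjusted over the list alone, and 5 rose and 1 fell over all genes with the patient block. Those that rose with the block included S100A8, S100A9 and NCF4, a subunit of the NADPH oxidase, at 127 ± 36.9 and 235 ± 26.6 CPM (adjusted p = 0.284, and 0.00199 with the block). The member that fell with the block was LGALS9, galectin-9, at 153 ± 62.9 and 83.7 ± 28.7 CPM (adjusted p = 0.628, and 0.00240 with the block). ARG1, arginase, had 0 counts in both groups, which allows up to 3 counts over a group. OLR1, the oxidised LDL receptor used to mark granulocytic suppressor cells, was 2.41 ± 3.19 and 0.705 ± 0.208 CPM and passed in neither fit. Without monocyte replicate 2 its log2 change went from -1.76 to 0.30. Checkpoint ligands and receptors were lower as a list with the preset correlation (16 measured, median log2 -0.29), a call lost with an estimated correlation (adjusted p = 0.543). With the preset one it was lost when a library was left out (0.297 without monocyte replicate 1 and 0.485 without M-MDSC replicate 3). Of them, 0 passed over all genes with edgeR, limma-voom or DESeq2, 3 had an unadjusted p under 0.05, and 0 passed adjusted over the list alone. With the block 2 fell, LGALS9 and LILRB4 (80.8 ± 22.0 and 47.2 ± 18.3 CPM, adjusted p = 0.634, and 0.0177 with the block), and 1 rose, SIRPA (153 ± 30.0 and 215 ± 33.7 CPM, adjusted p = 0.663, and 0.0389 with the block). Reactive oxygen and antioxidant genes gave no list call (22 measured, adjusted p = 0.729). Of them, 0 passed over all genes with edgeR or limma-voom or adjusted over the list alone, 6 had an unadjusted p under 0.05, and 1 rose with DESeq2. With the block 3 rose, among them NCF4, and 2 fell, among them SOD1 (154 ± 7.44 and 110 ± 8.61 CPM, adjusted p = 0.458, and 0.0487 with the block).

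Inflammatory genes moved in both directions with the patient block, and the list of NF-kB cytokines gave no call (19 measured, median log2 0.01, adjusted p = 0.685). Of its members, 0 passed over all genes with edgeR or limma-voom, 5 had an unadjusted p under 0.05, DESeq2 called 3 higher and 1 lower, 3 rose and 1 fell adjusted over the list alone, and 4 rose and 2 fell over all genes with the block. The neutrophil chemoattractants CXCL1 and CXCL8 rose with the block, from 11.1 ± 3.05 to 36.6 ± 13.3 CPM (adjusted p = 0.106, and 5.08e-04 with the block) and from 108 ± 35.6 to 235 ± 49.5 CPM (adjusted p = 0.183, and 0.00311 with the block). IL1B, the cytokine interleukin-1 beta, fell with the block from 167 ± 51.3 to 62.9 ± 20.4 CPM (adjusted p = 0.125, and 2.98e-04 with the block). Immediate early genes were lower as a list with the preset correlation (23 measured, median log2 -0.31), a call lost with an estimated correlation (adjusted p = 0.512). Over all genes 1 member fell, NR4A1, a nuclear receptor needed for non-classical monocytes, from 84.9 ± 24.1 to 22.6 ± 2.78 CPM (log2 -1.91 ± 0.24, adjusted p = 0.0174). This call was lost without monocyte replicate 1 or any 1 of the M-MDSC libraries. DESeq2 called 1 higher and 1 lower, and limma-voom 1 lower. An unadjusted p under 0.05 was reached by 7 members without the block and 14 with it. Adjusted over the list alone, 1 rose and 1 fell, and with the block 3 rose and 10 fell. Over all genes with the block 1 rose and 6 fell. The member that rose with the block was RGS2, at 1632 ± 410 and 2940 ± 458 CPM (adjusted p = 0.273, and 0.00199 with the block), and those that fell included KLF2, at 551 ± 237 and 234 ± 132 CPM (adjusted p = 0.483, and 1.56e-04 with the block).

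Interferon genes were lower as lists with the preset correlation, calls that were lost with an estimated correlation. For the type I interferon list (28 measured, median log2 -0.28) the adjusted p = 0.658 with an estimated correlation, and with the preset one it was 0.546 without monocyte replicate 1 and 0.555 without M-MDSC replicate 3. Of its members, 0 passed over all genes with edgeR, limma-voom or DESeq2, 2 had an unadjusted p under 0.05, 0 passed adjusted over the list alone, and 1 fell over all genes with the patient block. That 1 was ISG15, with a log2 change of -1.27 in the blocked fit (adjusted p = 0.871, and 0.0115 with the block). With the block, 11 members had an unadjusted p under 0.05 and 3 fell adjusted over the list alone. IFIT1 was 9.47 ± 1.29 and 3.35 ± 2.57 CPM and SIGLEC1 11.4 ± 6.29 and 5.34 ± 2.30 CPM, and neither passed in either fit. For the interferon-gamma list (19 measured, median log2 -0.43) the adjusted p = 0.526 with an estimated correlation, and 0.345 without monocyte replicate 1 with the preset one. Fry with the block called it lower (adjusted p = 0.0394). With the block, 13 of its members had an unadjusted p under 0.05 and 9 fell adjusted over the list alone. Of its members, 0 passed over all genes with edgeR or limma-voom, 4 had an unadjusted p under 0.05, 1 fell with DESeq2, 1 fell adjusted over the list alone (CIITA), and 5 fell over all genes with the block. Among these were the guanylate-binding protein GBP4, at 140 ± 107 and 60.4 ± 48.3 CPM (adjusted p = 0.772, and 4.02e-04 with the block), and WARS1, tryptophanyl-tRNA synthetase, at 588 ± 502 and 282 ± 170 CPM (adjusted p = 0.798, and 0.00302 with the block). CXCL9 was 2.85 ± 1.07 and 0.269 ± 0.307 CPM and passed in neither fit. For antigen processing on MHC class I (15 measured, median log2 -0.28) the adjusted p = 0.526 with an estimated correlation, and with the preset one it was 0.499 without monocyte replicate 1 and 0.262 without M-MDSC replicate 3. Of its members, 0 passed over all genes with edgeR (blocked or not), limma-voom or DESeq2 or adjusted over the list alone, and 1 had an unadjusted p under 0.05. TAP2 and CALR had log2 changes of -0.43 ± 0.17 and -0.44 ± 0.20.

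Glycolysis and hypoxia genes gave no list call without the patient block (26 measured, adjusted p = 0.130) and a higher one with it (adjusted p = 0.0242), lost with an estimated correlation in the blocked fit (adjusted p = 0.592). Of its members, 0 passed over all genes with edgeR or limma-voom, 4 had an unadjusted p under 0.05, 2 rose with DESeq2, 2 rose adjusted over the list alone and 4 over all genes with the block. The 2 were SLC2A3, a glucose transporter, at 439 ± 193 and 1078 ± 280 CPM (adjusted p = 0.262, and 3.19e-04 with the block), and HK2, hexokinase 2, at 72.1 ± 6.43 and 126 ± 28.7 CPM (adjusted p = 0.273, and 0.0119 with the block). Genes of oxidative phosphorylation were lower as a list with the preset correlation (42 measured, 39 of them below 0, median log2 -0.27), a call lost with an estimated correlation (adjusted p = 0.526). Of them, 0 passed over all genes with edgeR (blocked or not), limma-voom or DESeq2. Without the block 0 passed adjusted over the list alone and 4 had an unadjusted p under 0.05. With the block 2 fell adjusted over the list alone and 17 had an unadjusted p under 0.05. COX5A and COX7B, subunits of cytochrome c oxidase, had log2 changes of -0.53 ± 0.18 and -0.52 ± 0.19. Ribosomal protein genes were lower as a list with the preset correlation (37 measured, 35 of them below 0, median log2 -0.30), a call lost with an estimated correlation (adjusted p = 0.543). Fry with the block called this list lower (adjusted p = 0.0394). Of them, 0 passed over all genes with edgeR, limma-voom or DESeq2 or adjusted over the list alone, and 3 had an unadjusted p under 0.05. With the block 22 had an unadjusted p under 0.05, 16 fell adjusted over the list alone and 4 fell over all genes. Among these 4 was RPS19 (547 ± 36.2 and 387 ± 64.0 CPM, adjusted p = 0.534, and 0.0274 with the block). Lipid uptake and fatty acid genes gave no list call (23 measured, median log2 0.00, adjusted p = 0.980). Of them, 0 passed over all genes with edgeR, limma-voom or DESeq2 or adjusted over the list alone, 3 had an unadjusted p under 0.05, and with the block 2 rose and 1 fell. CD36, a fatty acid receptor, rose with the block, at 414 ± 74.1 and 666 ± 167 CPM (adjusted p = 0.477, and 0.00429 with the block), and FABP5 was 60.1 ± 9.54 and 39.5 ± 2.55 CPM and passed in neither fit.

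Transcription factors of the myeloid lineage gave no list call (30 measured, median log2 -0.02, adjusted p = 0.490), and NR4A1 alone fell, over all genes, adjusted over the list alone and with the patient block. IRF8, which directs precursors to the monocyte line, was 134 ± 27.6 and 98.2 ± 9.49 CPM (log2 -0.44 ± 0.20), and RB1, the retinoblastoma protein, was 73.7 ± 18.7 and 58.2 ± 4.44 CPM (log2 -0.34 ± 0.22). Neither passed in either fit (adjusted p = 0.713 and 0.862, and 0.134 and 0.457 with the block). Retinoblastoma and chromatin regulators (15 measured, adjusted p = 0.685), progenitor genes (8 measured, adjusted p = 0.980), unfolded protein response genes (23 measured, adjusted p = 0.22) and cell cycle genes (30 measured, adjusted p = 0.102) gave no list call either. In these 4 lists 0 members passed over all genes with edgeR, limma-voom or DESeq2 or adjusted over the list alone, and 1, 1, 1 and 0 members had an unadjusted p under 0.05. With the block 1 of them fell, ATF3, a stress-induced factor, at 42.1 ± 15 and 18.9 ± 8.47 CPM (adjusted p = 0.450, and 0.0156 with the block). The members with the smallest p were RBL2 (log2 0.55 ± 0.23), SOX4 (0.69 ± 0.30), CDK6 (-0.61 ± 0.28), E2F2 (-0.44 ± 0.23) and MCM5 (-0.31 ± 0.20), which passed in neither fit.

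Chemokine receptor and adhesion genes gave no list call (19 measured, adjusted p = 0.799), and members moved both ways with the patient block, 3 higher and 4 lower. Over all genes 0 passed with edgeR or limma-voom, 6 had an unadjusted p under 0.05, DESeq2 called 3 higher and 1 lower, and adjusted over the list alone 4 rose and 1 fell. ITGAM, the integrin chain CD11b, rose with the block, at 149 ± 30.4 and 287 ± 57.9 CPM (adjusted p = 0.183, and 6.47e-04 with the block).

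Markers of other blood cells gave no list call. The adjusted p was 0.729 for T cell markers (18 measured), 0.106 for B cell and plasma cell markers (8 measured), 0.980 for NK cell markers (12 measured), 0.799 for platelet markers (11 measured) and 0.980 for erythroid markers (4 measured). The basophil, mast cell and eosinophil list had 2 measured members, under the 3 needed for a list test. In these 6 lists 0 members passed over all genes with edgeR, limma-voom or DESeq2 or adjusted over the list alone, and 1 T cell and 1 B cell marker had an unadjusted p under 0.05. CLU, clusterin, rose with the patient block, at 20.9 ± 11.1 and 48.8 ± 42.3 CPM (adjusted p = 0.722, and 0.0205 with the block). The other members with the smallest p passed in neither fit: CD8B at 46.8 ± 9.22 and 31.3 ± 3.97 CPM, CD5 at 6.93 ± 1.04 and 11.9 ± 6.33 CPM, CD79B at 3.47 ± 1.66 and 0.519 ± 0.351 CPM, MZB1 at 11.4 ± 1.21 and 9.37 ± 1.82 CPM, GZMH at 2.32 ± 0.747 and 4.17 ± 1.67 CPM, CTSW at 6.38 ± 2.86 and 4.51 ± 0.513 CPM and ACRBP at 4.49 ± 1.39 and 1.74 ± 0.778 CPM. HBA1 and EPB42 were 3.49 ± 2.97 and 6.13 ± 7.08 CPM and 3.45 ± 1.78 and 2.72 ± 2.22 CPM, and the sign of both changed when a single library was left out.

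**Figure D3:**
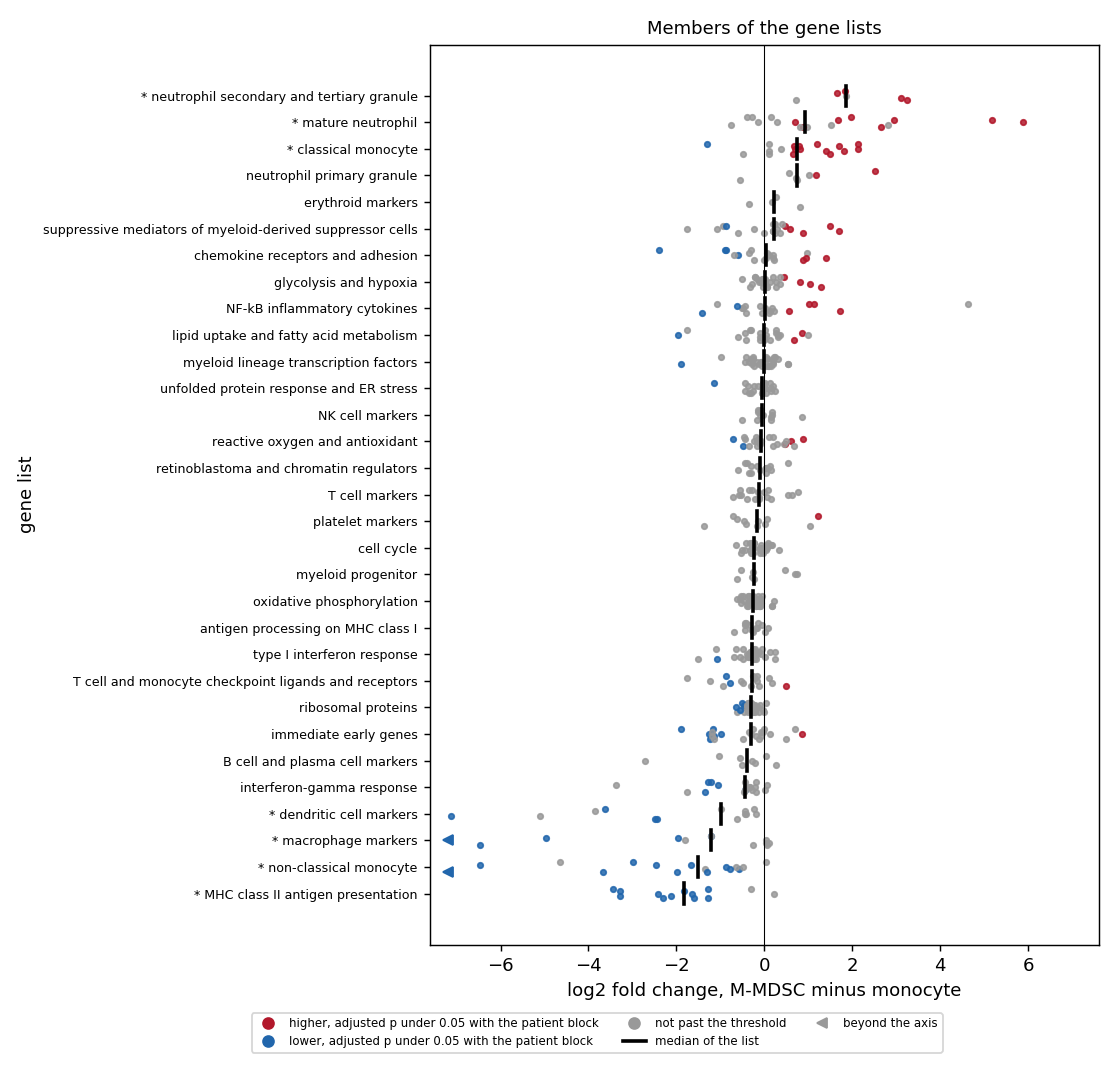
The log2 fold change of M-MDSC against monocytes without a patient term (x axis) is plotted for each measured member of the 31 gene lists with a list test (y axis), in red or blue for members past an adjusted p of 0.05 with the patient block and grey for the others, with a black bar at each list's median and an arrowhead for C1QB, which lies beyond the axis and whose fitted size depends on the prior count. An asterisk marks the 7 lists past an adjusted p of 0.05 with an estimated correlation, from MHC class II genes (median -1.82) at the bottom to neutrophil secondary and tertiary granule genes (median 1.85) at the top.

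Of the 31 lists tested, 16 passed with camera's preset correlation, 5 higher and 11 lower. The 7 that also passed with an estimated correlation, 3 higher and 4 lower, passed with fry as well. When the 6 libraries were split otherwise, the preset correlation called up to 17 lists. With the patient block the preset correlation gave 17 lists, fry 9 and the estimated correlation 0, with a lowest adjusted p of 0.0922 at 2 residual degrees of freedom. Fry with the block called the interferon-gamma and ribosomal protein lists (adjusted p = 0.0394 for both) besides those 7. The median, the mean and the test differed in sign for the lipid (median 0.00, mean -0.08), NK cell (-0.06, 0.03), reactive oxygen (-0.09, 0.04), chemokine receptor (0.04, -0.07) and erythroid lists, the last with a median of 0.22 and a lower direction in the test. With ENHO, C1QB and ORM1 set at their bound or ratio of counts, the medians of the dendritic, macrophage, non-classical and mature neutrophil lists stayed at -1.0, -1.22, -1.51 and 0.92. Of the genes named on the blocked result, HP, PROK2, VNN2, CSF1R, CDKN1C, VSIG4, CXCL8, SIRPA, ISG15, GBP4, WARS1, RGS2 and KLF2, as well as FCN1, CCR2 and CD163, were chosen after their values were seen.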

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

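Every alternative reported in this part was planned. Against 34 genes past the threshold, the count was 547 with the replicate block, 542 with the replicate block and DESeq2 size factors, 375, 422 and 556 with the block and pair 1, 2 or 3 left out, 401 with no filter, 214 with DESeq2, 62 at an adjusted p of 0.1 and 19 against a fold of 1.5. The block, no filter and DESeq2 kept all 34 genes. Leaving out single libraries gave 1 (without M-MDSC replicate 2, CYP1B1 among the named genes) to 37 genes (without monocyte replicate 2), with 2 without monocyte replicate 1, 10 without M-MDSC replicate 3, 22 without M-MDSC replicate 1 and 23 without monocyte replicate 3. These fits have fewer libraries, and the cause was not tested further. DESeq2 size factors gave 34 genes, the stricter filter 32 and limma-voom 33, of which 24 were shared and 60.6% higher, against 50% higher in the unblocked edgeR test. Of 29 named genes past the threshold, 346 alternative values gave 234 with the call kept, 112 with it lost and 0 with the sign turned. Of 52 named genes not past it, 616 values gave 558 with no call, 54 with a call and 4 with the sign turned. These were HBA1, 0.81 on the log2 scale and -0.62 to 1.39 with a library left out (-0.62 without M-MDSC replicate 2), EPB42, -0.35 and -1.11 to 0.14 (0.06 without monocyte replicate 3, 0.14 without M-MDSC replicate 3), and OLR1, -1.76 and -2.26 to 0.30 (0.30 without monocyte replicate 2), all at a few CPM, where the cause was not tested. Of the 16 lists, 7 passed with an estimated correlation and 7 with fry. With a library left out, 14 to 17 of all lists passed. These held all 16 except without monocyte replicate 1 (12 of the 16) and without M-MDSC replicate 3 (13 of the 16). The 208 alternative values of the 16 lists gave 183 with the call kept, 25 with it lost and 0 with the direction turned. Among the genes and lists reported, the replicate block changed no other call over all genes or list test than those given. Counts adjusted over a list alone or by unadjusted p were mostly higher with the block and are given with it for some lists only. The alternative for normalized values was not run, since counts were used. Of 19 secondary and tertiary granule genes, 13 were not among those tested, and a count of 0 allows up to 3 counts in a group.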

Other observations

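Further genes outside the lists, chosen after their values were seen, passed with the patient block. Among those higher in M-MDSC were CR1, a complement receptor (18.7 ± 14.1 to 60.2 ± 15.9 CPM, n = 3 per group, edgeR adjusted p = 4.57e-04 with the block and 0.300 without), AQP9, a glycerol and water channel (34.0 ± 19.6 to 101 ± 33.3 CPM, 1.82e-04 and 0.300), and CDA, cytidine deaminase (24.6 ± 13.7 to 81.7 ± 20.7 CPM, 1.50e-04 and 0.146). BST1, a surface enzyme of myeloid cells, rose from 107 ± 33.9 to 216 ± 31.8 CPM (5.02e-04 and 0.223), and CLEC4D, a C-type lectin receptor, from 32.6 ± 11.8 to 100.4 ± 8.03 CPM (4.00e-04 and 0.0542). IRS2, an adaptor of the insulin receptor, rose from 542 ± 414 to 1281 ± 792 CPM (1.66e-04 and 0.728). Lower in M-MDSC were CDKN1A, the cell cycle inhibitor p21 (328 ± 90.4 to 120 ± 38.8 CPM, 5.11e-05 and 0.103), CD83, an activation marker of antigen-presenting cells (225 ± 73.0 to 86.2 ± 41.5 CPM, 4.41e-05 and 0.252), and MTSS1 (109 ± 50.0 to 13.2 ± 12 CPM, 5.11e-05 and 0.110). The transcription regulators ID2 (1097 ± 373 to 465 ± 128 CPM, 4.41e-05 and 0.200) and RUNX3 (263 ± 46.3 to 127 ± 7.49 CPM, 2.98e-04 and 0.0650) fell as well, as did LIPA, lysosomal acid lipase (269 ± 57.6 to 107 ± 49.1 CPM, 7.89e-04 and 0.200). All of these had the same sign in the 3 pairs, which the blocked fit that called them favours.

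Of the tests below, those of carried-over granulocytes, of lost non-classical monocytes, of cell mixture behind the MHC class II genes, of TRIM34 and of the splits with an estimated correlation were chosen after the result was seen. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 34 genes and the highest other 0, and 1 split, the real one, reached 34. With the preset correlation the real split gave 16 lists and the others 17, 12, 11, 10, 10, 10, 7, 5 and 0, so that 2 splits reached 16. A call with the preset correlation alone therefore does not set the real groups apart from other splits. The split with 17 lists set both libraries of replicate 1 against both of replicate 3. Monocyte replicate 2 stood beside the former and M-MDSC replicate 2 beside the latter. With an estimated correlation the real split gave 7 lists and the highest other 0, and 1 split reached 7. The 4 ways to swap the labels within patients keep all pairs parted, and the 6 other splits put both libraries of a patient on the same side for 2 of the patients. With the block, the real labels gave 547 genes and the highest other swap 0, and 1 of the 4 reached 547, again too few for a share under 0.05. In lists with the block and the preset correlation, the real labels gave 17 and the other swaps 12, 7 and 1.

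The neutrophil genes that rose may come from the M-MDSC themselves or from other cells. Loss of non-classical monocytes as the sole cause stays open. If it raised all other monocyte genes alike, neutrophil genes and classical markers would have equal medians. In the patients the median log2 change of all 31 measured neutrophil genes was 1.25 and that of all 18 measured classical markers 0.78. The difference was 0.47 ± 0.13 (SD, n = 3), over 2 SD, which argues against an equal rise only. Markers that the lost cells also express would rise less, and CSF1R is on both monocyte lists, so an unequal rise does not decide the cause. The difference was wider, 1.74 ± 0.45, between 2 selected sets, the 14 of those 31 that rose with the block (2.15) and 7 of the 18 markers (0.42). Granulocytes carried over in the sort stay open. The summed rise of 9 transcripts abundant in neutrophils or their precursors (FCGR3B, CXCR1, CXCR2, ALPL, LTF, LCN2, CAMP, CEACAM8 and MMP8) was 8.42 ± 1.01 CPM against 81.0 ± 37.1 CPM for PADI4, a difference of -72.6 ± 38.0 (SD, n = 3), under PADI4 in all 3 patients but not by 2 SD. CXCR2 alone rose by 8.45 ± 3.20 CPM, so the others summed to about 0: CXCR1 and CAMP rose by 0.692 ± 0.696 and 0.887 ± 0.761 CPM, and FCGR3B, LTF, CEACAM8 and MMP8 changed by -0.583 ± 3.36, -0.172 ± 0.331, -0.420 ± 0.727 and -0.431 ± 0.746 CPM. CXCR2, CXCR1 and CAMP rose and these 4 had no clear rise, so the 9 transcripts do not decide on carried-over granulocytes. All 4 lie near the floor, and reads of FCGR3B can be assigned to FCGR3A. The change of FCGR3B varied between patients by more than its mean, and its log2 change in the blocked fit was 0.755 (adjusted p = 0.902). ALPL and LCN2 had 0 counts in all libraries, so their recovery here is unknown. That M-MDSC make these transcripts, as the series title's question of granulocyte precursors would have it, is a hypothesis that the design leaves untested.

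The fall of MHC class II genes may come from a sort on low HLA-DR, if that gate was used, which the labels do not state. It may also come from fewer non-classical monocytes and dendritic cells among the M-MDSC, or from lower expression in each cell. In the patients the median log2 change of 13 MHC class II genes was -1.97 and that of 29 non-classical and dendritic markers -1.58, a difference of -0.39 ± 0.27 (SD, n = 3), under 2 SD. Cell mixture and expression per cell cannot be told apart by this value, since RNA of sorted pools does not count cells.

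The rise of TRIM34 may come from read assignment or from a change in transcript use. The summed counts of TRIM34, TRIM6-TRIM34 and TRIM6 had a log2 change of -0.23 ± 0.35 (SE), within 2 SE of 0, which fits reads that moved between overlapping gene models in the authors' estimation. Of 21 measured read-through genes and their 35 measured component genes, 1 passed the threshold without the block and 2 with it. A biological change in transcript use at this gene would leave the sum unchanged as well, was not tested and stays open.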
